A study of Mus musculus with 6 samples.

How the data were processed

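PolyA RNA of 6 AdGFP-infected mouse PDAC cell lines was sequenced with a stranded kit in paired-end format, per the labels' protocols. Per the submitters' processing notes, reads were processed with TopHat2 2.0.10, Bowtie 1.0.0 and SAMtools 0.1.19 with the mm9 build, and DESeq2 was used. The counting tool, its gene annotation and any filter on low genes are not given in the sources used here. The deposited values are a signal per gene and sample, read counts divided by 1 size factor per sample, as the deposited column values show. Dividing a column by its smallest value above 0 gave whole numbers for 100% of values within a tolerance of 0.001, so reads were recovered, and size factors recomputed from them by DESeq2 equalled the deposited ones. The table held 14006 genes with at least 5 reads in total, no mitochondrial genes and no rows that name no gene. Paired fragments may have been counted once or per read, so reads here means the unit the authors counted.

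Library totals ran from 12653378 to 16309455 reads. Counting error at the median tested gene was 4.50% to 5.26%, and it covers counting only, since PCR copies are not independent molecules. Every pair of libraries differed by far more than sampling noise (chi-square over degrees of freedom 82.8 to 357), so all 6 were kept as separate samples. The labels do not say whether the lines came from separate animals. p-values therefore measure the spread between these lines.

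Gene names were matched to GENCODE M21 (GRCm38) by symbol for 13360 genes and by an older symbol for 540, and 106 were not matched. This annotation served for chromosome, gene order, exonic length and GC content, and no coordinates are printed because the authors used mm9. Exonic length is the union of all annotated exons of a gene. It can exceed the length of the transcripts expressed, so ratios divided by it depend on that choice. Genes were tested on log2(value + 1), so that fold changes of low genes are understated, where the mean was at least 10 (12570 genes). Each line was set against the other 5 with limma 3.58.1 (variance trend, Benjamini-Hochberg within a line at 0.05), which assumes that the lone library varies like the others. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 144 tests, and again with an estimated correlation. The 28 lists hold 340 symbols, of which 283 were in the table and 273 tested, and 24 lists had at least 3 tested members. They cover RAS-RAF-MEK-ERK kinases, MAPK output, EGFR family, JAK-STAT3, p53 targets, tumour suppressors, epithelial, mesenchymal, classical and basal-like genes, proliferation, interferon, antigen presentation, hypoxia, YAP-TEAD, NRF2, cytokines, adenovirus receptors, MYC family, sex-linked and reference genes, and markers of acinar, ductal, endocrine, fibroblast, leukocyte, endothelial and erythroid cells.

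The spread of a list was the median SD of its members over the 6 lines, with its percentile among 10000 random lists matched in 20 expression bins. Paralogs were compared within lines by exact two-sided sign-flip permutation over 64 sign assignments. Relations used all 720 pairings, two-sided. Genes off in a line had a value under 5 with a median of the other 5 of at least 100. Genes on had at least 100 in that line and under 5 in every other line, which is a stricter rule. The 28 lists, the tests of lines, lists, paralogs and relations, and the rule for named genes were fixed before the data were examined. Tests of explanations, a second list of fibroblast transcripts and the genes said to be named after their values were seen came later. Results of some genes fixed beforehand are not reported here, which leaves 4 of 9 paralog comparisons and 12 of 14 relations, with adjustment over all 9 and all 14. Named genes were Trp53, Egfr and the genes of the paralog comparisons, for each line up to 2 called genes in each direction with the largest difference, the 10 genes with the largest SD among those with a mean of at least 100, for each list the 2 members with the highest mean and the 2 with the largest SD, the measures of the relations, Cdkn2a, Cdkn2b, Mtap, Smad4, the sex-linked genes, and the genes of the off rule (all if 5 or fewer, otherwise the 3 with the highest median elsewhere).

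Alternatives were pseudocounts of 10 and 0.5, no filter or a mean of at least 50, quantile normalization, limma without trend, edgeR 4.0.16 (quasi-likelihood, deposited size factors or TMM) and DESeq2 1.42.0 on recovered reads, division by exonic length, the median in place of the mean as list score, other limits of the off rule, and each line left out. A loess correction for GC content and length, also of chromosome medians and of Egfr and Braf in line 3, and quantile normalization of the list tests, were added after the data were seen. Simulated data with 200 changed genes in 1 line were used to test the fits: limma found 0% of 8-fold and 72.0% of 64-fold changes, and edgeR 10.5% and 65.0%, with 27 and 4 false calls at 64-fold. In a test of the spread percentile on 12570 genes, a list with deviations made 3 times as large lay at the 100th percentile, and 6.00% of 200 random lists lay above the 95th. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and R 4.3.3, were used.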

Results

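RNA was sequenced from 6 mouse pancreatic ductal adenocarcinoma (PDAC) cell lines, each infected with an adenovirus that carries green fluorescent protein (AdGFP) at a multiplicity of infection of 25. The label of all 6 lines gives 1 genotype, which includes Trp53 flanked by frt sites that Flp recombinase uses, Egfr (the epidermal growth factor receptor) flanked by lox sites that Cre recombinase uses, and a tamoxifen-inducible Cre transgene. The lines are named here by their replicate number in the single group, line 1 to line 6. Each line was represented by 1 library, so the value of a line has no replicate of its own, and a line and its library are not separable. The labels give no second group and no batch, so the questions open to these data are at what level Trp53, Egfr and fixed gene lists were transcribed, how far the lines differed, and at which genes 1 line departed from the other 5. The table held normalized read counts of 14006 genes. Between 12653378 (line 2) and 16309455 (line 3) reads lay behind a library. The median gene tested had 362 reads in line 3 and 493 in line 4, which gives counting errors of 5.26% and 4.50%.

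Trp53, which encodes the p53 tumour suppressor, and Egfr were transcribed in all 6 lines. Trp53 had a mean normalized count of 2598 ± 762 (SD, n = 6) and ranged from 1526 in line 6 to 3773 in line 3. Egfr varied more, with a mean of 685 ± 611 and a coefficient of variation of 89.2%, against 29.3% for Trp53. Egfr was at 1815 in line 5 and 119 in line 3, a ratio of 15.3. It was also low in line 2, at 179, and lay between 577 and 716 in lines 1, 4 and 6. Long genes were low across the library of line 3 (Spearman correlation across genes of -0.34 between exonic length and the log2 difference from the mean of the other 5 lines), and Egfr has an exonic length of 11326 bases. Its log2 difference there was -2.38, and -1.67 after correction for GC content and length, when line 2 was lowest. The values of Trp53 were not corrected in this way. Both genes lie on chromosome 11. Counts were made per gene, so reads of recombined and intact alleles are added together in each value.

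**Figure D1:**
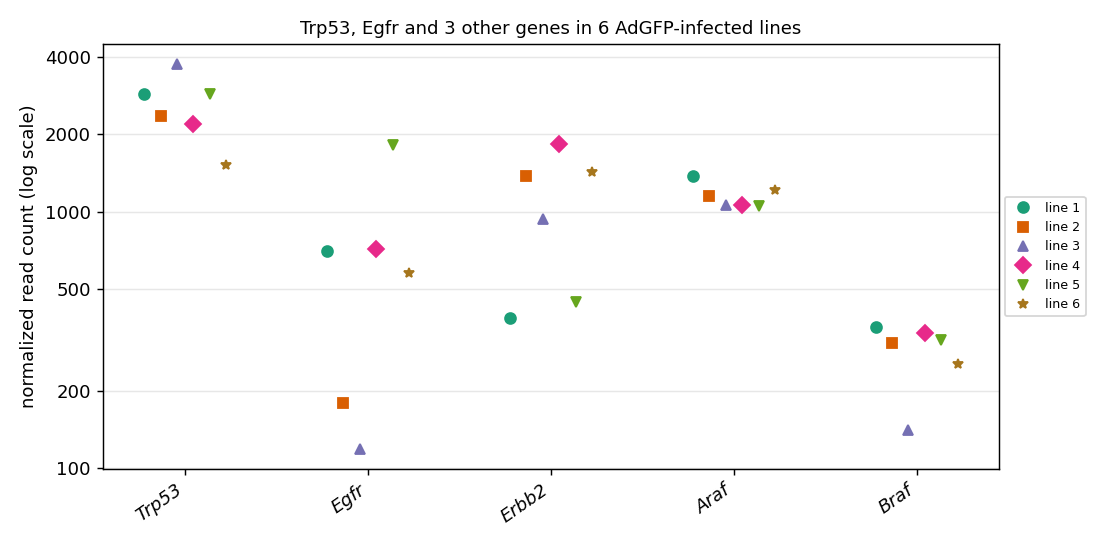
Normalized read counts (vertical log axis) of Trp53, Egfr and 3 other genes in the 6 lines, 1 point per line. Egfr ranges from 119 in line 3 to 1815 in line 5, and Braf stays below Araf in all 6 lines.

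Within each line related genes were set against each other. The kinase gene Araf exceeded Braf in 6 of 6 lines, with means of 1155 ± 128 and 286 ± 78.7 (SD, n = 6) and a mean log2 ratio of Braf to Araf of -2.07 ± 0.46. Braf, with an exonic length of 13862 bases, had a log2 difference of -1.14 in line 3, and -0.29 after that correction. Egfr exceeded its family member Erbb3 in 5 of 6 lines (mean log2 ratio 2.37 ± 2.84) and Erbb2 in 2 of 6 (-0.95 ± 2.02). The exact two-sided sign-flip permutation test gave p = 0.03125 for Braf against Araf, the smallest p that 6 lines allow, 0.0938 for Egfr against Erbb3 and 0.281 for Egfr against Erbb2. After Benjamini-Hochberg adjustment over the 9 comparisons computed, these became 0.0938, 0.169 and 0.316 in the exact test, so none passed 0.05. Divided by exonic length, the mean log2 ratio of Braf to Araf was -3.15 (exact permutation adjusted p = 0.0938). On that scale Egfr exceeded Erbb3 in 4 of 6 lines (mean log2 ratio 1.46, exact permutation adjusted p = 0.442) and Erbb2 in 1 of 6 (-2.07, adjusted p = 0.169). With 1 line left out, the ratio to Erbb3 lay between 1.42 (without line 1) and 3.01 (without line 6), and that to Erbb2 between -1.54 (without line 5) and -0.54 (without line 3). The ratio of Map2k1 to Map2k2, the genes of the MEK kinases, had a mean log2 of -0.47 (exact permutation p = 0.219, adjusted p = 0.281) and changed sign when counts were divided by exonic length, to 0.27. With 1 line left out it lay between -0.60 (without line 6) and -0.15 (without line 3).

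Among genes with a mean of at least 100, the 10 with the largest SD over the lines were Hnf4a, Gata5, Lgals2, Lgals4, Anxa10, Vsig1, Ugt2b34, Dmbt1, Col1a2 and Xist. Hnf4a, a transcription factor of endodermal epithelia, was at 3747 in line 2, 3993 in line 4 and 6369 in line 6, and at 0, 1.06 and 6.03 in lines 5, 3 and 1. Lgals4, an intestinal galectin, was at 10688, 31768 and 14409 in lines 2, 4 and 6, and at 35.2, 28.6 and 11.2 in lines 1, 3 and 5. Anxa10, Vsig1, Gata5, Ugt2b34, Lgals2 and Dmbt1 were likewise at 2.12 or below in lines 1, 3 and 5, and reached 7228 for Anxa10 in line 6 and 11327 for Lgals2 in line 2. Over all genes, an average-linkage tree put lines 1, 3 and 5 on 1 branch and lines 2, 4 and 6 on the other. Pearson's r across genes lay between 0.874 and 0.940 for the 6 pairs within a branch and between 0.814 and 0.872 for the 9 pairs between branches. Genes are not independent replicates, and the branches come from the data, so they were not tested as groups.

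Of 18 epithelial genes, 11 had their lowest value in line 1. Cdh1, which encodes the adhesion protein E-cadherin, was at 38.2 there and 317 in line 3, against 15849.7 in line 2 and 15358 in line 6. The keratin gene Krt7 was at 62.3 in line 1 and 29483 in line 2, while Krt18 ranged from 6386 in line 5 to 57469 in line 2. These genes do not stand for the list, since line 2 held the highest value of 4 of the 18 genes and line 4 that of 7. The median value of the 18 genes was 96.5 in line 2 and 828 in line 4. The list of 18 epithelial genes lay lower in line 1 than in the other 5 lines, with a mean log2 difference of -4.30 (limma camera, adjusted p = 5.44e-12), and higher in line 4, with a mean difference of 2.48 (adjusted p = 2.00e-06). With an estimated correlation the adjusted p was 0.834 in both lines. In line 1, 8 of the 18 genes were lower when adjusted over the list alone and 0 when adjusted over all genes tested.

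Classical PDAC genes, a list that marks the gland-like subtype, were high in lines 2, 4 and 6. Muc1, a mucin, was at 16173 in line 6, 7578 in line 2 and 2719 in line 4, and at 47.7, 51.3 and 193 in lines 3, 1 and 5. Of 13 tested members, 10 had their highest value in line 6. The list passed the camera test in each line, higher in lines 2 (mean log2 difference 3.81, adjusted p = 0.00222), 4 (3.79, 0.000117) and 6 (4.77, 0.000117) and lower in lines 1 (-3.75, 0.00751), 3 (-4.29, 0.0325) and 5 (-4.34, 0.000300), the library with high fibroblast markers. With an estimated correlation the adjusted p lay between 0.834 and 0.874. The call in line 3 was lost without line 2, 4 or 6, with adjusted p up to 0.0910. The 6 comparisons share their libraries, so a list that is high in some lines is low in others by construction.

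In line 5, 9 of 16 mesenchymal genes and 8 of 9 fibroblast and stellate cell markers had their highest value. Col1a1 and Col1a2, the chains of type I collagen, were at 21778 and 12502 in line 5. They were at 4678 and 1802.9 in line 6, and in the other 4 lines the 2 genes were at most 195 and 21.2. Other markers were shared more widely. Col3a1 was at 5673 in line 5, 4065 in line 1 and 3573 in line 3. Pdgfrb was at 2117 in line 5 and 1200 in line 3. Col3a1 and Pdgfrb were named after their values were seen. Lox, a collagen crosslinking enzyme, was at 3379.5 in line 5 and at most 159.8 elsewhere, and Thy1, a fibroblast surface marker, at 2498 and at most 39.5. Fn1, which encodes fibronectin, was higher in line 1 (69693) than in line 5 (49208), and Vim, which encodes vimentin, was highest in line 3 (55089). In line 5 the 16 mesenchymal genes had a mean log2 difference of 2.71 (limma camera, adjusted p = 2.90e-05) and the 9 fibroblast and stellate cell markers one of 6.97 (adjusted p = 3.16e-09), of which 5 were higher when adjusted over the list alone and 0 over all genes. Both lists were lower in line 4 (-2.12, adjusted p = 2.00e-06; -4.83, adjusted p = 2.13e-06) and in line 2 (-2.01, adjusted p = 0.00354; -3.49, adjusted p = 0.0153). The fibroblast call in line 2 was lost without line 6 (adjusted p = 0.126), and with an estimated correlation the adjusted p of these 6 calls was 0.834. Of the 18 epithelial genes, line 5 held the highest value of 2, a value among the top 2 lines for 7 and the lowest of 3, among them Krt8 (6831) and Krt18 (6386). The list had a median log2 difference of 1.65 there, with no call (mean 0.76, limma camera adjusted p = 0.936).

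**Figure D2:**
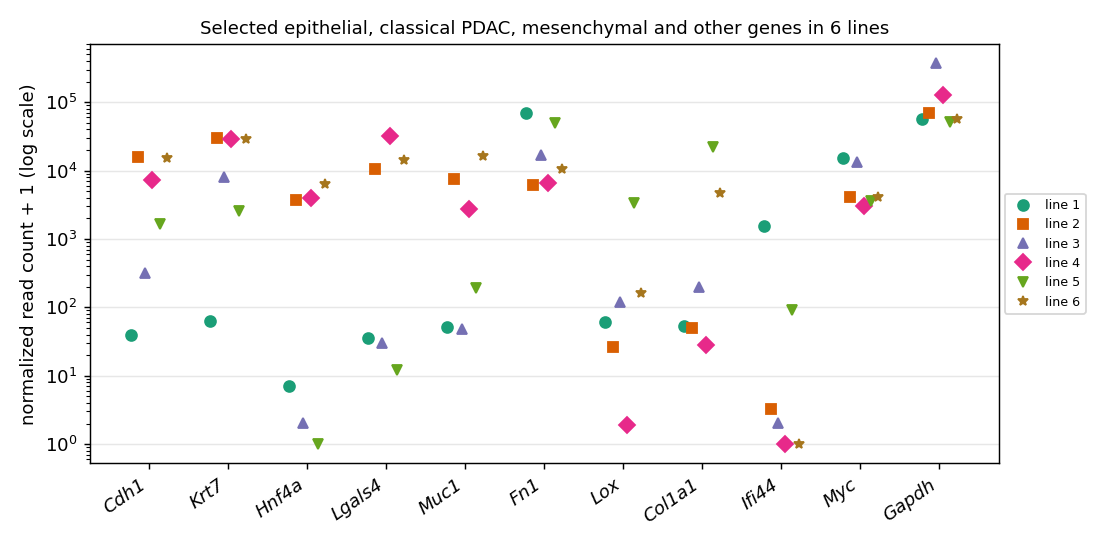
Normalized read counts plus 1 (vertical log axis) of 11 genes in the 6 lines, 1 point per line. Hnf4a, Lgals4 and Muc1 are high in lines 2, 4 and 6, Col1a1 and Lox are highest in line 5, Ifi44 in line 1 and Gapdh in line 3.

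Spp1, which encodes osteopontin, was abundant in all lines, from 16349 in line 1 to 90110.1 in line 6, and the progenitor marker Prom1 from 1.01 in line 1 to 1898 in line 2. The 8 ductal cell markers were lower in line 5, the library with high fibroblast markers (mean log2 difference -1.66, limma camera adjusted p = 0.00354), with 2 lower when adjusted over the list alone, and higher in line 4 (1.58, adjusted p = 0.0153), where the call was lost without line 1 (adjusted p = 0.0540). With an estimated correlation the adjusted p was 0.834 for both. Sprr1a, a gene of squamous epithelium, was lowest in line 5 and at 93504 in line 6, while the list of 8 basal-like or squamous genes passed in no line. Among leukocyte markers Cd14 was at 3003 in line 2 and 2533 in line 6, and 3 of the 5 members in the table reached the mean of 10, again with no call. Acinar, endocrine and endothelial markers had 1, 2 and 1 members with a mean of at least 10 and the 5 erythroid genes none, so these lists were not tested. The acinar elastase gene Cela1 was at most 179 (line 6), the endocrine genes Isl1 and Pax6 at most 103 (line 5) and 76.2 (line 4), and the endothelial gene Esam at most 60.9 (line 2).

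Of 16 interferon-stimulated genes, which cells switch on in antiviral responses, 15 had their highest value in line 1. Every line was infected with AdGFP and there was no uninfected library. A response to the virus therefore cannot be told from a level present without it. Ifi44 was at 1520.0 in line 1, 90.2 in line 5 and at most 2.30 in the other 4, and Ifit3 was at 724, 45.6 and at most 14.9. Bst2 ranged from 164 in line 2 to 5079.8 in line 1. The list had a mean log2 difference of 4.84 there (limma camera, adjusted p = 3.38e-14), with 12 of 16 genes higher when adjusted over the list alone and 0 over all genes. It was also higher in line 5, the library with high fibroblast markers (2.08, adjusted p = 0.0112), and lower in lines 3 (-2.60, adjusted p = 0.0188) and 4 (-2.23, adjusted p = 0.000185). With an estimated correlation these adjusted p were between 0.834 and 0.874. The call in line 5 was lost without line 3 (adjusted p = 0.0901), and that in line 3 without line 1 or 5 (up to 0.0837).

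B2m, the light chain of class I molecules, was at 8936 in line 1 and 786 in line 4, and H2-K1, a class I heavy chain, was lowest in line 3, at 323 against 1498 to 2440.1 in the others. The 9 antigen presentation genes were higher in line 1 (mean log2 difference 1.81, limma camera adjusted p = 0.000421) and lower in line 3 (-1.95, adjusted p = 0.00922), with 2 lower in line 3 when adjusted over the list alone. With an estimated correlation the adjusted p was 0.834 for both. Class I genes are near-identical copies of each other, so their separate counts are uncertain. Cxadr, the receptor to which adenovirus type 5 binds, ranged from 702 in line 3 to 2909.7 in line 2, and the 4 adenovirus receptor genes measured passed in no line.

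In line 5, 7 of 12 JAK-STAT3 signalling genes, 8 of 14 cytokines and chemokines, 7 of 16 MAPK output genes and 9 of 12 YAP-TEAD target genes had their highest value. The list named YAP-TEAD target genes also holds the regulators themselves, Yap1, Wwtr1 and Tead1, so it does not measure target genes alone. Lif, a cytokine that acts through STAT3, was at 3179 there and at most 695 elsewhere, and Osmr, the oncostatin M receptor, at 1399 and at most 235. The growth factor Csf1 was at 18867 in line 5 and 3038 in line 1, Ccl2 at 7559 and 742, and Cxcl12 at 7495 in line 5 and 549 in line 6. In line 5 the limma camera test called the 12 genes of JAK-STAT3 signalling higher (mean log2 difference 1.15, adjusted p = 0.000517), the 14 cytokines and chemokines (2.79, adjusted p = 4.85e-05), the 16 MAPK output genes, which ERK signalling induces (0.67, adjusted p = 0.00766), and the 12 YAP-TEAD target genes (1.06, adjusted p = 0.000296). In the same library the 9 fibroblast and stellate cell markers had a mean log2 difference of 6.97, with 8 of 9 highest there. Adjusted over the list alone, 5 cytokines and 1 JAK-STAT3 gene were higher, and over all genes 0. Each of these 4 had an adjusted p of 0.834 with an estimated correlation. Cyr61, a YAP-TEAD target, was at 25327 in line 5 and 1139 in line 4. The YAP-TEAD list was lower in line 3 (-0.87, adjusted p = 0.00634), and cytokines were lower in line 4 (-1.43, adjusted p = 0.0149), a call lost without line 6 (adjusted p = 0.0514). The adjusted p of both was 0.834 with an estimated correlation. The 15 RAS-RAF-MEK-ERK kinases and the 10 genes of the EGFR family and its ligands passed in no line.

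Top2a, the topoisomerase of dividing cells, ranged from 4224 in line 6 to 9625 in line 1, and the mitotic kinase gene Aurka from 929 to 3726. The 14 proliferation genes were higher in line 1 (mean log2 difference 0.66, limma camera adjusted p = 0.000900) and lower in lines 2 (-0.76, adjusted p = 1.71e-05) and 6 (-0.85, adjusted p = 7.23e-06), each with an adjusted p of 0.834 with an estimated correlation. Myc was at 15159.9 in line 1 and 13391 in line 3, and between 3004 and 4138 in the other 4. Of the tumour suppressor genes often lost in PDAC, Cdkn2a was at 16897 in line 3 and between 2269.8 and 4553 elsewhere. Values in the library of line 3 varied with exonic length, and that of Cdkn2a was not corrected for it. Cdkn2b, Mtap and Smad4 were transcribed in all 6 lines, with means of 1310.4 ± 554, 2693 ± 1239 and 1277 ± 309.5 (SD, n = 6). The 14 p53 target genes were higher in line 2 (0.71, adjusted p = 0.0202; adjusted p = 0.834 with an estimated correlation). The 3 MYC family genes and the 15 tumour suppressors passed in no line.

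Gsta4, a glutathione transferase, ranged from 56.3 in line 1 to 22559 in line 6, and Me1, malic enzyme, from 1335 in line 3 to 10269 in line 6. The 11 NRF2 target genes were higher in line 2 (mean log2 difference 1.06, limma camera adjusted p = 0.00235), and the 14 hypoxia and glycolysis genes lower in line 4 (-0.36, adjusted p = 0.0359). Both had an adjusted p of 0.834 with an estimated correlation, and the hypoxia call was lost without line 2, 3 or 6 (adjusted p up to 0.220). Car9, which hypoxia induces, was at 307 in line 2 and at most 28.2 elsewhere. Gapdh, often used as a reference gene, was at 369506 in line 3, where it took 2.14% of reads, and between 51338 and 129469 in the other 5. Of its 24 nearest expressed genes on chromosome 6, 18 were also above 2-fold in line 3. Actb had a mean of 65522 ± 12345 (SD, n = 6), and the 10 reference genes passed in no line. That does not make them steady, since in line 3 7 of the 10 had their highest value and 3 their lowest. These values were not corrected for GC content and length. The list test averages such opposite moves.

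Over all 24 lists with at least 3 tested members, 34 of 144 tests passed, 17 higher and 17 lower, and none with an estimated correlation (smallest adjusted p = 0.834, with 6 unadjusted p under 0.05). Mean, median and test had the same sign in all 34, and 27 of the 34 passed whichever other line was left out. In line 3, where long genes were low, the 4 lists called were all lower. Each of the 4 was still lower after correction for GC content and length.

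**Figure D3:**
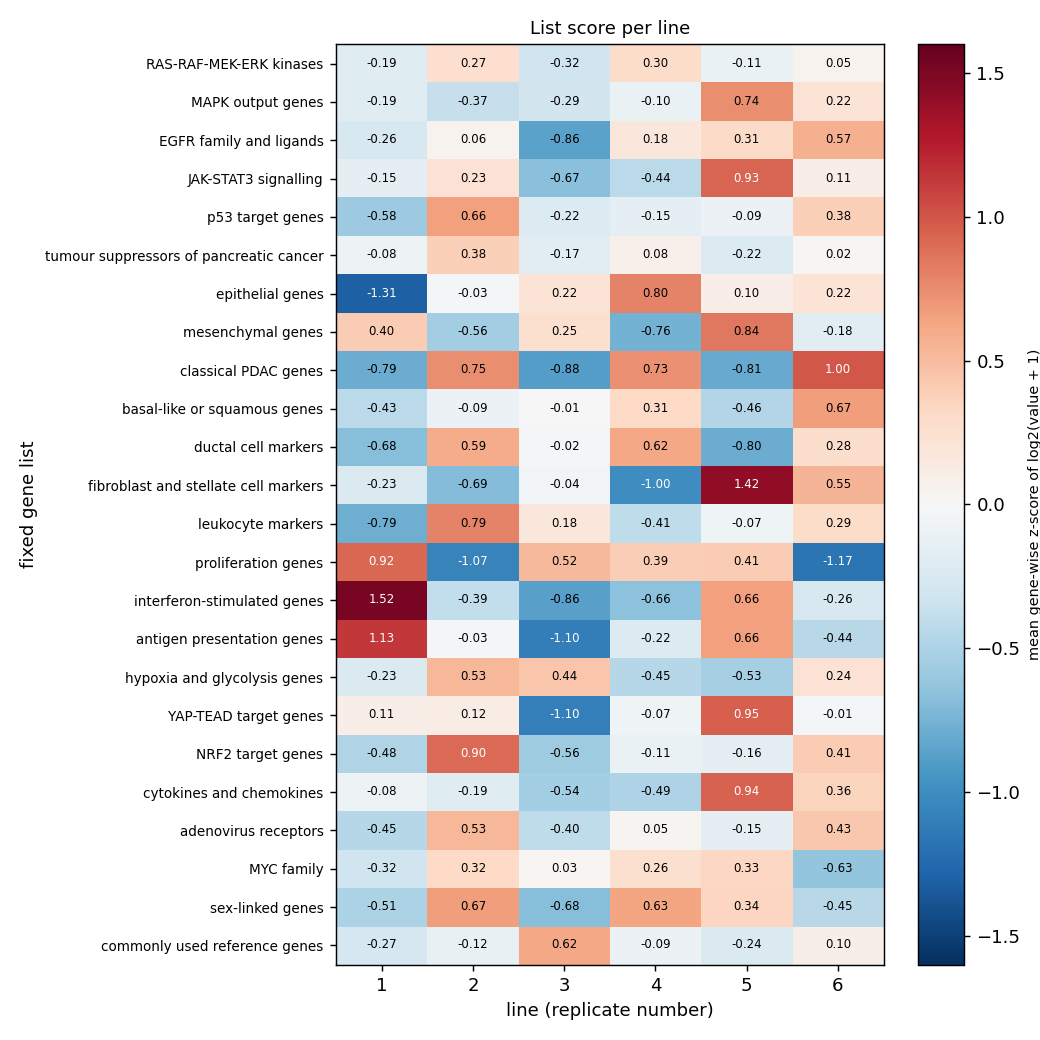
Score of each of the 24 fixed gene lists (rows) in the 6 lines (columns), as the mean over members of the z-score of log2(value + 1) across the lines, with no unit. The scores of interferon-stimulated genes in line 1 (1.52), fibroblast markers in line 5 (1.42) and epithelial genes in line 1 (-1.31) lie farthest from 0.

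Classical PDAC genes had a median SD of 4.07 on the log2 scale, fibroblast markers 4.26, epithelial genes 2.62, interferon-stimulated genes 2.51, cytokines and chemokines 2.23, basal-like or squamous genes 2.28 and mesenchymal genes 1.97. Random lists matched on mean expression had a median of 0.81, 1.09, 0.65, 1.26, 1.02, 1.5 and 0.59, in the same order. Of 24 lists, 16 lay above the 95th percentile of 10000 such random lists. The others above it were the sex-linked genes, NRF2 targets, ductal markers, EGFR family and ligands, YAP-TEAD targets, JAK-STAT3 signalling, MAPK output, proliferation genes and adenovirus receptors. Below it were antigen presentation (94.8th percentile), p53 targets (90.2), tumour suppressors (87.7), hypoxia and glycolysis (73.2), leukocyte markers (71.7), the MYC family (69.4), reference genes (39.7) and the RAS-RAF-MEK-ERK kinases (28.7). The place of 7 lists against the 95th percentile rested on single lines. Without line 3, adenovirus receptors lay at 67.8, basal-like or squamous genes at 82.8 and YAP-TEAD targets at 91.5. Without line 5, JAK-STAT3 signalling lay at 89.1, YAP-TEAD targets at 91.9, tumour suppressors at 95.7 and antigen presentation at 96.2. Without line 6, proliferation genes lay at 83.6, basal-like or squamous genes at 92.5 and antigen presentation at 97.8, without line 1 adenovirus receptors at 91.2, and without line 2 antigen presentation at 97.1. The percentile describes these libraries and is not a p-value.

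Sex-linked genes differed between the lines. Xist, the RNA that coats the inactive X chromosome of female cells, was at 3662 in line 1, 1893 in line 3 and 121 in line 6, and at most 4.59 in the other 3. The Y-linked gene Ddx3y was at 584, 526 and 372 in lines 2, 4 and 5 and at most 8.46 in the others. Of the other Y-linked genes, Eif2s3y was at 545, 548 and 234 in lines 2, 4 and 5, and Kdm5d and Uty were at least 113 and 88.4 there and at most 2.82 and 2.82 in the others.

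On the log2(value + 1) scale, 5 departures of 1 line from the other 5 passed, all of them lower values. In line 3 these were Auts2 (0 against a mean of 332.5, log2 difference -8.33 ± 0.58 SE, adjusted p = 0.0350), Zbed6 (2.12 against 421.7), Slc25a13 (3.18 against 501) and Vopp1 (11.7 against 664), the last 2 named after their values were seen. In line 5 it was Hmgcll1, a ketogenic lyase (0.930 against 603, log2 difference -8.22 ± 0.61 SE, adjusted p = 0.0267). Lines 1, 2, 4 and 6 had no gene past the limma test. edgeR called 0 genes in each line, except 1 in line 6 with the deposited size factors, and DESeq2 called 223, 28, 905, 21, 101 and 26 genes in lines 1, 2, 3, 4, 5 and 6. In data simulated with the spread of these lines, limma found 0% of genes changed 8-fold in 1 line and 72.0% of those changed 64-fold, with 27 false calls among 171. Each call was lost when any 1 of the other lines was left out, and no call in line 3 passed after quantile normalization. In every other line Auts2 was at least 202, Zbed6 at least 227, Slc25a13 at least 363 and Hmgcll1 at least 409. The test picks out genes with such a gap, so these values add no support to the calls. Across genes, exonic length and the log2 difference of line 3 had a Spearman correlation of -0.34, against 0.06 to 0.14 in the other lines, and of the 4 genes called in line 3, Auts2 and Slc25a13 passed after correction for GC content and length.

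Many genes were off in 1 line, with a value under 5 where the median of the other 5 was at least 100. There were 123 such genes in line 1, 101 in line 3, 57 in line 5, 29 in line 2, 19 in line 4 and 12 in line 6. The protease gene Tmprss2 was at 1.01 in line 1 and up to 3249.6 in line 6. Mlph and Anxa13 were at 2.79 and 0.930 in line 5, and up to 6007 and 6562 elsewhere. In line 2 the BMP antagonist gene Grem1 was at 3.44, against 5488 in line 1 and 6158 in line 5, and Mrc2 was at 3.44. Slpi and the collagen receptor gene Ddr2 were at 1.75 in line 4, and Tgfbr3 was at 0 in lines 2 and 4. In line 6 the rule named Aldh1a2, Hhip and Eif2s3y. All other lines exceeded 100 for only 1 of the 123 genes of line 1 and 6 of the 101 of line 3, so most of these genes were low in further lines too. Genes on in a line met a stricter rule, at least 100 there and under 5 in every other line. Off and on counts are therefore not comparable. The on genes numbered 10. They were Fam101a in line 2, Grap in line 3, and Ildr1 and Nlrp6 in line 4. Entpd1, Eya4 and Irx1 were on in line 5, and Ano7, Crtam and Ly6d in line 6. Their values ranged from 117 (Fam101a) to 497 (Crtam).

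Relations between pathways were computed across the 6 lines for 14 pairs fixed beforehand, and none passed adjustment over the 14. Interferon-stimulated and antigen presentation genes were closest (Pearson's r = 0.93, exact permutation p = 0.00556, adjusted p = 0.0778; Spearman's rho = 0.83, exact permutation p = 0.0583), and r was 0.65 without lines 1 and 5. JAK-STAT3 signalling and cytokines had r = 0.92 (exact permutation p = 0.0111, adjusted p = 0.0778) and rho = 0.83 (exact permutation p = 0.0583), with r = 0.63 without lines 3 and 5. Egfr and MAPK output genes had r = 0.81 (exact permutation p = 0.0514, adjusted p = 0.240) and rho = 0.77 (exact permutation p = 0.103), with r = 0.82 without lines 2 and 3. Myc and proliferation genes had r = 0.51 (exact permutation p = 0.246) and rho = 0.49 (exact permutation p = 0.356), with r = -0.89 without lines 1 and 3. Cxadr and interferon-stimulated genes had r = -0.20 (exact permutation p = 0.668) and rho = -0.03, with r = -0.85 without lines 2 and 3. In none of the 14 pairs did both measures separate the branches of the tree.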

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

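All tests of explanations in this part were chosen after the results they examine were seen. Of 156 measures, 17 had 1 line set apart from the other 5 by a gap that was large against the whole range (Dixon's ratio at its 95% limit), where chance alone gives about 1 in 20, or 7.8. Of the 17, 13 are genes named because 1 line departed from the others, so their gaps carry no added evidence. Without genes named for that reason, 4 of 129 measures were set apart (Braf, Cdkn2a, H2-K1 and the share of the 10 most abundant genes), where chance gives 6.5.

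In line 3 the ratio of gap to range on the log2 scale was 0.880 for Auts2, 0.838 for Zbed6, 0.758 for H2-K1 and 0.638 for Braf (0.0163 after correction for GC content and length), all low, and 0.653 for Cdkn2a and 0.657 for Grap, both high. Among these genes the ratio after that correction was computed for Braf alone. The share of reads taken by the 10 most abundant genes was also highest in line 3, at 7.95% against 4.91% to 5.78% in the others (ratio 0.713). Hmgcll1 was low in line 5 (0.872). Genes high in 1 line were Fam101a in line 2 (0.719), Ildr1 (0.714) and Nlrp6 (0.786) in line 4, Entpd1 (0.814), Eya4 (0.726) and Irx1 (0.672) in line 5, and Ano7 (0.685), Crtam (0.740) and Ly6d (0.875) in line 6.

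Gapdh was at 369506 in line 3 and at most 129469 in the others. Reads shared with Gapdh pseudogenes would leave its neighbours unmoved, yet 18 of its 24 nearest expressed genes were above 2-fold in line 3, and correction for GC content and length left their median log2 difference at 2.11 (2.13 before). That median lay above the highest 25-gene median of 100 shuffled gene orders (0.898). A stretch of chromosome 6 was drawn outward from Gapdh while the running median of neighbouring genes stayed above 2-fold. It reached from Lpcat3 to Tapbpl. Its 22 of 25 genes above 2-fold follow largely from that rule, and Iffo1 in it was at -2.81. Among the nearest genes beyond Tapbpl, values ran from -0.62 (Plekhg6) to 3.94 (9630033F20Rik), so its ends need not be those of a gain. A gain around Gapdh may account for the level, as a hypothesis found and tested on the same data, since DNA copy number was not measured. Neighbours were at a median of 0.56 in line 4 and below 0 in the other 4 lines. The lines that each of these was set against include line 3, which lowers these medians. Beyond a gain no biological explanation was tested.

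Long genes were low in line 3, with a Spearman correlation across genes between exonic length and the log2 difference of -0.34, against 0.06 to 0.14 in the other 5. The 10% of genes with the shortest exons in total had a median difference of 0.65 and the 10% with the longest one of -0.71. GC content alone does not carry the trend, since within 10 bins of GC content the correlation was -0.2011 or lower, and neither does abundance, since within 10 bins of mean expression it was -0.1892 or lower. RNA or library quality could not be examined with 1 library per line and no read positions, and no biological explanation was tested. Correction for GC content and length took the genes at an unadjusted p under 0.05 in line 3 from 1886 to 1256.

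Collagen and other fibroblast genes were high in line 5. The median of all tested genes differed by 0.0177 and that of the markers by 7.21. Size factors hold the median of all genes near 0 in every line by construction, so it could not show a scaling shift. A size factor moves all genes of a library alike, so it does not by itself set the markers apart from other genes. Fibroblasts mixed into the culture may contribute and stay open: of 14 tested genes on a second list of abundant fibroblast transcripts, most of whose values had been seen when it was written, so that it is no independent check, 85.7% were at least 3 times the median of the other lines, among them Bgn (29979 against a median of 118), Postn and Col5a2, but not Pcolce or Igfbp7. Tumour cells with mesenchymal genes on express these transcripts too, and fibroblasts also express Cxcl12, Ccl2, Csf1, Osmr and Cyr61, so the source of the cytokine, JAK-STAT3, MAPK output and YAP-TEAD values of line 5 stays open as well. No biological explanation was tested.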

How the results depend on the processing

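The corrections for GC content and length, and quantile normalization of the list tests, were chosen after seeing the data. No paired analysis was possible because the labels give 1 group. Of 517 alternative values, 449 kept their direction, their side of the threshold and about their size, 66 moved and 2 reversed; of the 66, 15 concern single lists, relations, genes or chromosomes. Quantile normalization shifted the median log2 difference of all genes to 0.12 in lines 1 and 3 and -0.11 in line 6, from within 0.03 of 0. Depth limits genes near the floor of 3 reads, which is 2.63 to 3.44 normalized counts. The cause was not tested for any change below, except that leaving out a line removes samples.

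Counts of genes called rested on the tool. DESeq2 gave 223 in line 1, 28 in line 2, 905 in line 3 (242 higher, 663 lower), 21 in line 4, 101 in line 5 and 26 in line 6, against 0, 0, 4, 0, 1 and 0 by limma. It held the 4 genes of line 3 and the 1 of line 5. In line 3 the count was 0 with a pseudocount of 10, with quantile normalization, with limma without trend and with edgeR under both scalings, 2 with GC and length correction, and 0 to 0 with any other line left out. In line 5 it was 0 with a pseudocount of 10 and with edgeR under both scalings, 2 with a pseudocount of 0.5, quantile normalization, a mean of at least 50, limma without trend and GC and length correction, and 0 to 0 with any line left out. edgeR with the deposited size factors gave 1 in line 6.

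With an estimated inter-gene correlation 0 lists passed in lines 1, 2, 3, 4, 5 and 6, against 5, 6, 4, 8, 9 and 2 with the preset one. Leaving out a line gave 2 to 4 lists in line 6, with 4 without line 3 or line 5. Quantile normalization gave 3 higher and 4 lower in line 1 (3 and 2 before), 5 and 3 in line 2 (3 and 3) and 5 and 4 in line 4 (3 and 5). All 34 list calls passed after GC and length correction. The number of lists above the 95th percentile was 13 to 17 with 1 line left out, against 16.

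The log2 ratio of Map2k1 to Map2k2 reversed to 0.27 when divided by exonic length, and the r of Cdkn2a and p53 target genes to 0.0920 with quantile normalization. Genes off in lines 1, 2, 3, 4, 5 and 6 numbered 25, 11, 27, 10, 37 and 2 with an upper limit of 1, and 199, 60, 175, 37, 91 and 28 with a median of the others of at least 50.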

Other observations

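The comparisons in this part were chosen after the data were seen. Myc was highest in lines 1 and 3, and its neighbour Pvt1, a noncoding RNA gene, was at 2417 and 4506 there and at most 186 in the other 4. Fam84b was at 14250.1 in line 1 and 455 in line 3. Both genes were chosen after their values were seen. Clu, which encodes the secreted chaperone clusterin and was also chosen after its values were seen, was at 145067 in line 6, where it was the most abundant gene, 70030.3 in line 2 and 44487 in line 4, and at most 4918 in the other 3.

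Whole chromosomes differed between lines. Relative to the other 5 lines, the median log2 difference of chromosome 14 was -0.61 in line 2 (415 genes), of chromosome 12 -0.47 in line 5 (432 genes), of chromosome 18 0.49 in line 6 (323 genes), of chromosome 13 0.42 in line 1 (459 genes), of chromosome 3 -0.47 in line 3 (617 genes) and of chromosome 8 -0.38 in line 4 (697 genes). Each lay outside 1000 random draws of as many genes. Between 5 and 10 of the 19 autosomes lay outside their draws in each line. Long genes were low in line 3, and after correction for GC content and length these 6 medians were -0.62, -0.50, 0.47, 0.31, -0.34 and -0.36, in the same order, each again outside draws from the corrected values. In line 3, 7 autosomes lay outside before and 7 after, of which 4 (chromosomes 2, 3, 4 and 7) did so in both. In line 1 the number went from 5 to 9. Genes of 1 chromosome are not independent, and DNA was not measured. Chromosome X had a median of -0.61 in line 3 and 0.39 in line 1, both of which expressed Xist, and of -0.42 and 0.32 after that correction.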
